A study of Mus musculus with 12 samples.

How the data were processed

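RNA was measured in 12 libraries of the E14 mouse ES cell line, prepared with a stranded poly(A) library kit. A first table holds 8 libraries, EPSC and 3dESC each in the arms DMSO, DES, siNT and siEsrrb, and a second holds 4 untreated libraries, EPSC and 1, 2 and 3 days in ES cell medium. Groups were read from the sample labels, and each has 1 library. The authors deposited FPKM values (read fragments scaled by transcript length and by the mapped fragments of the library), and their notes name STAR and the mm9 genome. The tool that made the FPKM values, the annotation, the versions and any further scaling between libraries are not given in the sources used here. Each table has 24819 gene rows with symbols and 0 columns of values without a sample. The 2 tables were taken as separately normalized, so FPKM levels were not compared across them, only directions and log2 ratios taken within a table.

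Values were analysed as log2(FPKM + 1), for genes with a mean of at least 1 FPKM over the table, 11783 in the first and 11726 in the second. The tables hold no counts, so no counting interval could be given. A few genes withheld for evaluation are not reported here. Relative depth was read from the smallest step between values under 0.1 FPKM, which is inverse to depth for a gene of given length. The state effect (3dESC against EPSC), the siEsrrb effect (against siNT) and the DES effect (against DMSO) were fitted with limma 3.58.1 in R 4.3.3, with an intensity trend, as additive terms for 4 arms and 2 states. The fit leaves 3 residual degrees of freedom, which hold the state-by-arm interaction, so a treatment effect that differs between states widens the spread. Benjamini-Hochberg adjustment was over all genes of an effect, with a threshold of 0.05, and tests were against change in either direction.

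Within 1 state a treated library was compared with its own control library by log2 ratio, counted at 2-fold, with no p. An alternative fixed in advance took the DMSO and siNT libraries of a state as 2 replicates of 1 control, fitted 6 groups with limma and left 2 residual degrees of freedom. It assumes that a lone treated library varies like the controls and that vehicle and siNT cultures are alike. The 39 gene lists, with 851 members of which 7 matched no symbol, cover pluripotency states, other cell types, signaling targets, metabolism, stress, estrogen response, chromatin, imprinting, proliferation and housekeeping. For fitted effects, members past the threshold were counted over all genes and adjusted over the list alone. Limma's camera was run with a preset correlation of 0.01 and again with an estimated correlation, each adjusted over the lists. A list said to be called by camera passed with the preset. The preset treats members as nearly independent, so its p does not measure spread between cultures. The estimated correlation was 0.85 for 2-cell-like and 0.74 for primitive endoderm genes. With it camera called no list for the state effect or the siEsrrb effect over both states (lowest adjusted p 0.321 and 0.294). Correlated members alone do not account for this. For the state effect the estimated correlation was 0.0026 for formative and -0.0064 for epithelial genes, below the preset. Their unadjusted camera p still went from 7.05e-07 to 0.0132 and from 6.51e-06 to 0.0165. This version rests on the few residual degrees of freedom, so a list failing it is not shown to be unchanged. Limma's fry, planned beside camera, tests members without setting them against other genes and was adjusted over the lists. For the state effect its adjusted p was 0.00711 for formative, epithelial and Hox, 0.0153 for germ line and 0.0263 for ERK genes. For primitive endoderm it was 0.0355, and for 2-cell-like and p53 genes, which did not pass, 0.148 and 0.155. For siEsrrb over both states fry called no list (lowest adjusted p 0.0651). For single-library ratios the list median was set against the medians of 10000 random lists drawn from 20 bins of mean expression.

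Lists, design, alternatives and the rule for named genes were fixed before the data were examined. The rule takes, for a fitted effect, the 12 largest rises and the 12 largest falls past the threshold that go the same way in every arm or state (and in the time course for the state effect). For a single-library ratio it takes the 8 highest and 8 lowest genes with a mean of at least 5 FPKM, without unnamed, ribosomal, small and pseudogene models, and from each list up to 4 members with the largest change. Alternatives were pseudocounts of 0.1 and 5, a minimum of 5 FPKM or none, centring of libraries, quantile normalization, no trend, a further 2-fold threshold, control libraries only, no arm term, leaving out arms or libraries, and other sources of the time course lists. Added after seeing the data were the tests of the difference between states, the test of DES minus siEsrrb, the comparison of DMSO with siNT cultures, and the time course lists in EPSC.

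Simulated data had 200 of 11783 genes changed, 100 by 2-fold and 100 by 4-fold. The state, siEsrrb and DES fits and the pooled test of siEsrrb in 3dESC were tried on them. The other pooled tests, those of the difference between states, that of DES minus siEsrrb and camera were not tried. The changed genes were well expressed, noise was independent between genes, and a fitted change was the same in every state or arm. The state fit recovered 100% of 2-fold changes, the siEsrrb fit 85%, the DES fit 89% and the pooled test in 3dESC 61%. At 4-fold the shares were 100% for the fitted effects and 99% for the pooled test. False calls among the unchanged genes numbered 15, 9, 11 and 7 in the same order. Real effects that differ between states can be recovered less often than these shares. Among 200 simulated lists of 20 genes without a shift, 7.5% lay outside the central 95% of random medians, and 99.5% of lists shifted by 0.5 log2 lay above it. Ratios and figures were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.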

Results

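The data are gene-level RNA-seq values from 12 libraries of E14 mouse embryonic stem (ES) cells, taken as cells grown in a medium for expanded potential stem cells (EPSC) were moved back into ES cell medium with LIF and serum. The EPSC medium holds LIF and inhibitors of MEK, GSK3, JNK, p38, Src-family kinases and tankyrase. The first table has 8 libraries, EPSC and cells after 3 days in ES cell medium (3dESC), each with DMSO, with diethylstilbestrol (DES, a synthetic estrogen that also binds estrogen-related receptors), with a non-targeting siRNA (siNT) or with an siRNA against Esrrb (siEsrrb). The second table is a time course of 4 untreated libraries, EPSC and 1, 2 and 3 days in ES cell medium. Each condition has 1 library, so no value has a replicate error. Values are FPKM computed by the authors. Genes are identified by symbol; the genome build behind the tables, mm9, is not among the references used here, so no coordinates are given.

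Between 15766 and 16553 genes were above 0 FPKM per library in the first table and between 16173 and 16329 in the second. Summed FPKM ran from 553948 to 618984 and from 601054 to 644343, and the 10 most abundant genes took 7.39 to 8.59% and 8.50 to 9.59% of it. The tables give no counts, so absolute depth is unknown. The smallest step between low values, which a single read sets, was up to 1.44-fold apart among the first 8 libraries, with 3dESC siEsrrb the shallowest and EPSC siEsrrb the deepest, and up to 1.23-fold apart in the time course.

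Esrrb, the orphan nuclear receptor that the siRNA targets, was measured first in every library. In 3dESC it stood at 166 FPKM with siNT and 53.2 with siEsrrb, 67.9% lower (log2 ratio -1.62). In EPSC the values were 144 with siNT and 101 with siEsrrb, 29.8% lower (log2 ratio -0.51). With DES it stood at 90.6 against 137 FPKM with DMSO in 3dESC, 33.8% lower, and at 146 against 147 in EPSC, 0.516% lower. With the DMSO and siNT libraries of a state taken as replicates, the fall in 3dESC passed the limma test under siEsrrb (adjusted p = 0.00228) and under DES (adjusted p = 0.0316), and that in EPSC did not (adjusted p = 0.451 under siEsrrb). The untreated libraries had 145, 133, 147 and 161 FPKM from EPSC to day 3.

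**Figure D1:**
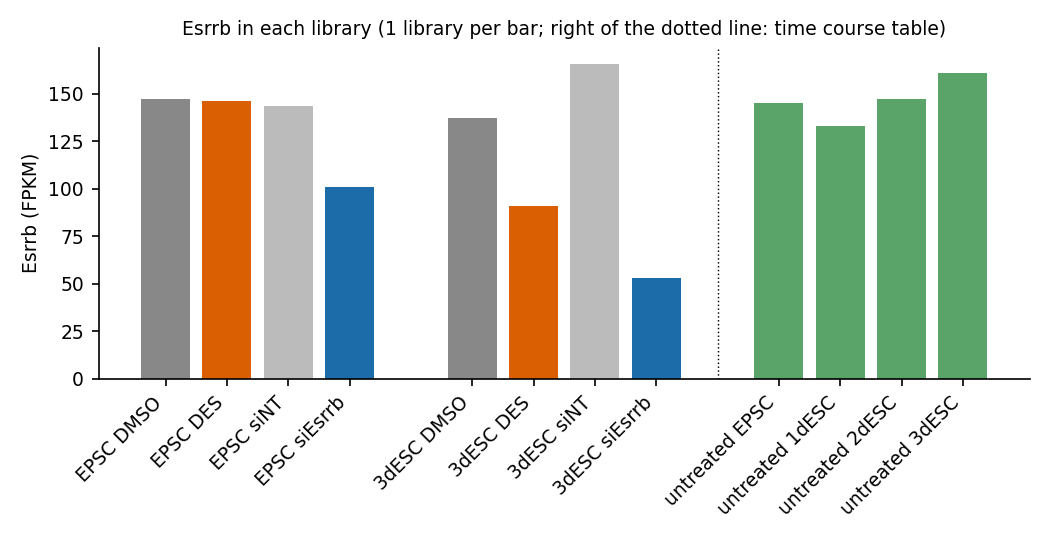
Bars give the FPKM of Esrrb (vertical axis, from 0) in each of the 12 libraries, with the time course table right of the dotted line and no error bars since each bar is 1 library. The lowest bar is 3dESC siEsrrb at 53.2 FPKM, against 166 in 3dESC siNT.

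The first comparison asks which genes differ between 3dESC and EPSC on average over the 4 arms. Markers of primitive endoderm and targets of ERK were among the largest rises in 3dESC. Cubn and Amn, the subunits of an endocytic receptor, rose by log2 5.09 ± 0.35, adjusted p = 0.000303 and by 4.02 ± 0.23, adjusted p = 0.000166, and Dab2, an endocytic adaptor, by 4.20. Dusp4, a MAP kinase phosphatase, rose by 4.32 ± 0.19, adjusted p = 7.04e-05, and Myc by 3.40. Germ line genes were among those that fell most: Stra8, needed for entry into meiosis, fell (-5.25 ± 0.15, adjusted p = 2.93e-05), as did Dazl (-3.35). The water and glycerol channel gene Aqp3 (-5.14 ± 0.16, adjusted p = 2.93e-05) and the kinase gene Aurkc (-3.50) fell too.

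The further genes with the largest rises were Spink1 (4.36), Foxq1 (3.77), Srgn (3.71), Amot (3.71), Trh (3.62), Car4 (3.44) and Lamb1 (3.40), where Trh encodes thyrotropin-releasing hormone and Lamb1 a laminin chain. The further genes with the largest falls were Ly6a (-4.33), Tuba3b (-3.90), Nkain4 (-3.03), H2-Bl (-2.94), Calcoco2 (-2.94), Tuba3a (-2.83), Crxos (-2.82) and Dsp (-2.70). Tuba3a and Tuba3b are near copies of each other and H2-Bl has close relatives, so reads can pass between them and their single values are uncertain. In the limma fit with arm and state as terms, 1550 genes rose and 2087 fell of 11783 tested at an adjusted p under 0.05 (5076 at an unadjusted p under 0.05), and 861 of them also changed at least 2-fold. Rises and falls numbered 1877 and 1713 with libraries centred on their medians and 1660 and 1863 with quantile normalization, so which side is larger depends on scaling. The residual spread has 3 degrees of freedom and holds any difference between arms in the state effect. The count was 2332 with the 4 control libraries alone, 2102 without the siEsrrb arm, 2328 without the DMSO arm and 2365 without the siNT arm.

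Targets of ERK, BMP, Wnt and YAP signaling rose more often than they fell. Of the ERK targets, 15 of 22 measured members rose, 0 fell and 7 did not pass (16 rose and 0 fell when adjusted over the list alone), among them Spry4 (3.15) and Dusp6 (2.45), both feedback inhibitors of the pathway. The ERK list had a camera adjusted p = 1.11e-07, and adjusted p = 0.513 with an estimated correlation. Among BMP and Id genes, 6 of 13 measured members rose, 2 fell and 5 did not pass (7 rose and 2 fell when adjusted over the list alone), with Id1 (3.32), Id3 (3.21) and Id2 (2.00). The BMP and Id list had a camera adjusted p = 0.00673, and adjusted p = 0.513 with an estimated correlation. For Wnt targets, 6 of 14 measured members rose, 1 fell and 7 did not pass (9 rose and 2 fell when adjusted over the list alone), with Dkk1 (2.74), Axin2 (1.60) and Lef1 (1.54). The Wnt list had a camera adjusted p = 0.00673, and adjusted p = 0.513 with an estimated correlation. In the YAP list 8 of 15 measured members rose, 1 fell and 6 did not pass (9 rose and 1 fell when adjusted over the list alone), with Ctgf (1.70) and Amotl2 (1.63). The YAP list had a camera adjusted p = 0.000642, and adjusted p = 0.513 with an estimated correlation. Its median difference between states was 0.32 in the DMSO arm and 0.61 in the siNT arm, against 0.82 with DES and 1.00 with siEsrrb. LIF and STAT3 targets split: 6 of 16 measured members rose, 4 fell and 6 did not pass (7 rose and 4 fell when adjusted over the list alone), with Gbx2 (2.28), Junb (1.65) and Tfcp2l1 (-1.15), and so did Nodal targets, where 2 of 12 measured members rose, 3 fell and 7 did not pass (2 rose and 3 fell when adjusted over the list alone), with Lefty1 (-1.42). Camera called neither of these (adjusted p = 0.168 and 0.844), though it called the LIF and STAT3 list up from the 4 control libraries (adjusted p = 0.0160, and 0.853 with an estimated correlation).

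Pluripotency genes did not move as a block. In the naive list 4 of 25 measured members rose, 10 fell and 11 did not pass (4 rose and 13 fell when adjusted over the list alone; camera adjusted p = 0.136), with Gbx2 (2.28) and Tdh (1.84) up and Prdm14 (-2.01) and Nanog (-1.79) down. The naive median difference between states was -0.18 in the DMSO arm and -0.16 in the siNT arm, both inside the ranges of random lists. It was -0.85 with DES and -0.70 with siEsrrb, so the treated arms weigh on the naive falls. In the time course the naive median was -0.24, outside the -0.18 to 0.16 of random lists. In the core list 9 of 17 measured members rose, 1 fell and 7 did not pass (9 rose and 1 fell when adjusted over the list alone), with Foxd3 (2.23) and Lin28a (1.96). The core list had a camera adjusted p = 0.00132, and adjusted p = 0.576 with an estimated correlation. In the formative and primed list 12 of 20 measured members rose, 1 fell and 7 did not pass (13 rose and 1 fell when adjusted over the list alone), with the DNA methylation genes Dnmt3l (2.35) and Dnmt3b (2.29) and with Pou3f1 (2.23) and Zic2 (-1.88). The formative list had a camera adjusted p = 9.17e-06, and adjusted p = 0.321 with an estimated correlation. Of the 2-cell-like genes, a set of copy-rich families transcribed in the early embryo, 8 of 16 measured members rose, 0 fell and 8 did not pass (14 rose and 0 fell when adjusted over the list alone), such as Zscan4c (1.55). The 2-cell-like list had a camera adjusted p = 5.08e-05, and adjusted p = 0.576 with an estimated correlation. With the 4 control libraries alone 0 of 16 rose (0 rose and 0 fell when adjusted over the list alone; median 0.28, camera adjusted p = 0.0806). The median difference between states was 0.032 in the DMSO arm and 0.55 in the siNT arm, against 1.66 with DES and 1.74 with siEsrrb.

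Markers of other cell types moved apart. Of the primitive endoderm markers 20 of 22 measured members rose, 0 fell and 2 did not pass (21 rose and 0 fell when adjusted over the list alone), with a median log2 change of 2.80. The endoderm list had a camera adjusted p = 6.36e-13, and adjusted p = 0.513 with an estimated correlation. With the 4 control libraries alone 18 of 22 measured members rose, 0 fell and 4 did not pass, at a median of 1.92, and in the time course the median was 0.64 over 16 measured members. In the germ line list 4 of 20 measured members rose, 9 fell and 7 did not pass (4 rose and 9 fell when adjusted over the list alone). The germ line list had a camera adjusted p = 0.0109, and adjusted p = 0.576 with an estimated correlation. Trophoblast markers went both ways: 5 of 20 measured members rose, 6 fell and 9 did not pass (5 rose and 7 fell when adjusted over the list alone; camera adjusted p = 0.940), with Rhox6 (-2.09), Sox21 (-1.82) and Tfap2c (-1.76). For mesoderm, 4 of 6 measured members rose, 1 fell and 1 did not pass (4 rose and 1 fell when adjusted over the list alone), with Fgf17 (2.25) and Snai1 (1.85). The mesoderm list had a camera adjusted p = 0.0271, and adjusted p = 0.513 with an estimated correlation. For neural genes, 0 of 5 measured members rose, 4 fell and 1 did not pass (0 rose and 5 fell when adjusted over the list alone), with Nes (-1.38) and Sox1 (-1.21). The neural list had a camera adjusted p = 0.00861, and adjusted p = 0.513 with an estimated correlation. Of the Hox genes 0 of 8 measured members rose, 6 fell and 2 did not pass (0 rose and 6 fell when adjusted over the list alone), with Hoxa5 (-2.02) and Hoxa3 (-1.70). The Hox list had a camera adjusted p = 0.00180, and adjusted p = 0.513 with an estimated correlation. In the feeder and fibroblast list 2 of 7 measured members rose, 2 fell and 3 did not pass (2 rose and 2 fell when adjusted over the list alone; camera adjusted p = 0.844).

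Imprinted genes rose more often than they fell: 14 of 22 measured members rose, 4 fell and 4 did not pass (15 rose and 5 fell when adjusted over the list alone), with Cdkn1c (2.69) and Phlda2 (2.42). The imprinted list had a camera adjusted p = 0.000278, and adjusted p = 0.513 with an estimated correlation. The epithelial list had Esrp1 (2.57) and Cldn7 (1.67) among the rises, and 10 of 18 measured members rose, 1 fell and 7 did not pass (12 rose and 1 fell when adjusted over the list alone). The epithelial list had a camera adjusted p = 5.08e-05, and adjusted p = 0.321 with an estimated correlation. In the mesenchymal list 4 of 17 measured members rose, 7 fell and 6 did not pass (7 rose and 7 fell when adjusted over the list alone; camera adjusted p = 0.940). Stress genes included 8 rises and 0 falls of 21 in the integrated stress response list (9 rose and 0 fell when adjusted over the list alone), such as Atf3 (1.04) and Asns (0.76). The integrated stress list had a camera adjusted p = 0.000326, and adjusted p = 0.513 with an estimated correlation. Among p53 targets 8 of 23 measured members rose, 1 fell and 14 did not pass (10 rose and 1 fell when adjusted over the list alone), with Ddit4l (1.53) and Plk2 (1.51). The p53 list had a camera adjusted p = 0.000326, and adjusted p = 0.591 with an estimated correlation. Its median difference between states was 0.069 in the DMSO arm, 0.45 in the siNT arm and 0.21 with siEsrrb, against 1.37 with DES. The DES arm thus weighs on the p53 rises.

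Falls outnumbered rises among genes of oxidative phosphorylation and lipid synthesis. Of the oxidative phosphorylation genes 1 of 57 measured members rose, 15 fell and 41 did not pass (1 rose and 15 fell when adjusted over the list alone), with Ndufs8 (-0.61) and Sdhb (-0.52). The oxidative list had a camera adjusted p = 0.000745, and adjusted p = 0.576 with an estimated correlation. For cholesterol synthesis 1 of 25 measured members rose, 10 fell and 14 did not pass (1 rose and 10 fell when adjusted over the list alone), with Tm7sf2 (-0.77) and Fdps (-0.71), and for fatty acid synthesis 2 of 17 measured members rose, 10 fell and 5 did not pass (2 rose and 10 fell when adjusted over the list alone), with Thrsp (-1.68) and Acss2 (-1.27). The cholesterol list had a camera adjusted p = 0.00254, and adjusted p = 0.576 with an estimated correlation. The fatty acid list had a camera adjusted p = 0.0374, and adjusted p = 0.576 with an estimated correlation. In the time course the cholesterol median was -0.14, inside the -0.21 to 0.15 of random lists. The fatty acid median there was -0.37, outside their -0.27 to 0.18. Camera did not call the lists that follow, whose adjusted p values ran from 0.110 to 0.791. Glycolysis had 1 rise and 3 falls of 21 (Hk1 (-1.70)), the tricarboxylic acid cycle 2 and 3 of 18, and hypoxia genes 3 and 5 of 18. Interferon genes had 3 rises and 5 falls of 9, the unfolded protein response 3 and 0 of 18, heat shock genes 3 and 1 of 15 (Cryab (2.42)), and NRF2 and AHR targets 2 and 0 of 11. Several of these lists depended on the treated arms. From the 4 control libraries alone glycolysis had 7 rises and 2 falls (9 rose and 2 fell when adjusted over the list alone; median 0.49, against -0.012 in the full fit). Its camera adjusted p was 0.00689 there, up, and 0.675 with an estimated correlation. The oxidative phosphorylation list had 0 rises and 1 fall from those controls (0 rose and 0 fell when adjusted over the list alone; camera adjusted p = 0.102), and its time course median was -0.020. Hypoxia and unfolded protein response medians changed sign, to 0.20 and -0.24, the mesoderm list was no longer called (camera adjusted p = 0.0636), and NRF2 and AHR targets were, as higher (adjusted p = 0.0395, and 0.853 with an estimated correlation).

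Counted in the same way as rises and falls, the estrogen and estrogen-related receptors with their cofactors had 0 and 2 of 8, with Esrra (-0.55) among the falls. Estrogen targets had 1 and 2 of 11, genome architecture genes 1 and 2 of 24, DNA methylation genes 4 and 5 of 14 (Uhrf1 (-0.71)), Polycomb genes 4 and 7 of 20 (Epop (1.14) and Aebp2 (-1.12)), proliferation genes 3 and 6 of 21 and housekeeping genes 1 and 0 of 16. Camera called none of these (adjusted p from 0.119 to 0.820). Adjusted over the list alone, the counts of rises and falls in these lists and in those for glycolysis, hypoxia and stress were within 3 genes of those over all genes. The median, the mean and the camera direction differed in sign for the feeder list (median 0.061, mean -0.0052, camera up) and for glycolysis (median -0.012, mean -0.091, camera up).

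The untreated time course asks when these genes move. Trh stood at 10.1, 73.0, 101 and 264 FPKM in EPSC and at days 1, 2 and 3, Spry4 at 0.816, 20.7, 32.1 and 37.0, and Dusp4 at 0.542, 6.62, 13.4 and 21.7. The DNA methylation genes were high by day 1: Dnmt3l stood at 29.4, 246, 379 and 341 FPKM and Dnmt3b at 3.86, 28.0, 33.9 and 42.9. Myc stood at 0.0955, 3.86, 7.31 and 9.53 FPKM. On the falling side Stra8 stood at 122, 38.6, 18.1 and 4.72, Aqp3 at 299, 126, 37.9 and 16.7 and Dazl at 60.2, 46.6, 11.2 and 3.80 FPKM, while Ly6a was higher at day 1 and then lower, at 36.1, 107, 6.78 and 0.423.

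Also among the 8 lowest at day 3 were Tuba3b (-3.30), Col9a2 (-3.27), Vax2 (-3.17) and Aurkc (-2.97), as log2 ratios of day 3 over EPSC. Rpph1, an RNA component of RNase P, was among the 8 highest with 0, 5.54, 2.93 and 13.8 FPKM, but short RNAs without a poly(A) tail are measured poorly by a poly(A) kit and its value is uncertain. Of 11726 genes, 402 were at least 2-fold higher at day 3 and 458 at least 2-fold lower. Among the higher genes 158 had reached 2-fold by day 1, 127 first did so at day 2 and 117 at day 3, and among the lower genes the counts were 83, 117 and 258. Each time has 1 library, so these differences have no replicate check and no p.

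By list, 11 of 20 formative and primed genes were at least 2-fold higher at day 3 (median log2 ratio 1.23, against -0.28 to 0.18 for the central 95% of random lists of matched expression). ERK targets had 11 of 21 (median 1.16), imprinted genes 9 of 19 (median 0.87) and core pluripotency genes 7 of 17 (median 0.71). Germ line genes were lower, 8 of 22 at least 2-fold (median -0.81). No member of the 2-cell-like list reached the expression minimum there. Of 3477 genes called in the state fit and measured in both tables, 3242 (93.2%) had the same direction at day 3 of the time course, against 8575 of 11422 (75.1%) over all genes in both tables. The integrated stress response list, with its rises in the state fit, had a median of -0.19 in the time course, inside the -0.21 to 0.17 of random lists.

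**Figure D2:**
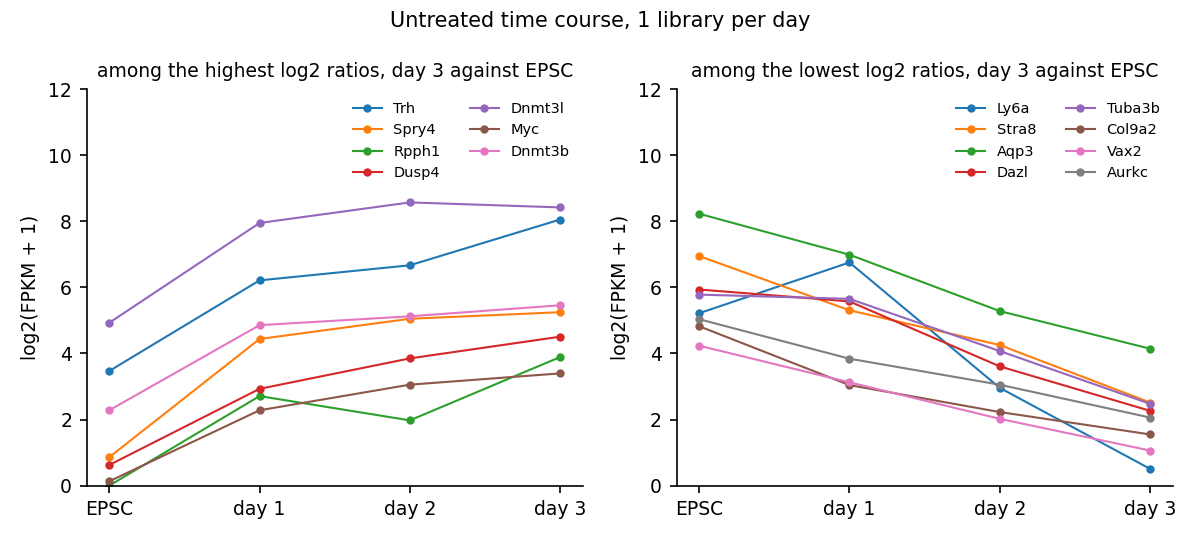
Lines give log2(FPKM + 1) (vertical axis) of 7 genes among the highest and the 8 genes with the lowest day 3 over EPSC ratio, in EPSC and after 1, 2 and 3 days in ES cell medium (horizontal axis, days), 1 library per time. Dnmt3l goes from 29.4 to 341 FPKM and Stra8 from 122 to 4.72.

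The next comparison asks what lower Esrrb does as cells leave the EPSC state, siEsrrb against siNT in 3dESC. The 2-cell-like list was the highest: all 16 of 16 measured members were at least 2-fold higher (median log2 ratio 3.23), with Zscan4a (3.63), Zscan4c (3.54), Zscan4d (3.51), Zscan4f (3.47) and Tdpoz4 (3.49). The filter on mean FPKM kept 16 list members, partly because they were high in the treated libraries; without it 22 of 24 members with a value were at least 2-fold higher (median 2.77). Primitive endoderm markers were higher as well, 19 of 22 at least 2-fold (median 1.83), among them Dab2 and Cubn of endocytosis (2.36 and 2.35), Lrp2 (2.16) and Foxa2 (2.11), an endoderm transcription factor. Naive pluripotency genes were lower, 11 of 25 at least 2-fold (median -0.88), with Esrrb itself among them and Jam2 (-1.72) and Tcl1 (-1.50), while Dppa3, a maternal and germ line factor, was higher (2.37). Nanog had a log2 ratio of -1.06 and Tfcp2l1 of -1.38.

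The other genes among the 8 highest were Hotairm1 (3.80), Lgals2 (3.33), Rhox6 (2.84) and Spink1 (2.76). Those among the 8 lowest were Ldhb (-1.86), Ndufa4l2 (-1.85), A2m (-1.82) and Rec114 (-1.80), which passed the limma test with pooled controls, and Rpph1 (-2.40), Amd1 (-2.32), Khdc3 (-2.12) and Inhbb (-2.02), which did not. Ldhb encodes a lactate dehydrogenase subunit. Hotairm1 and Rpph1 are non-coding, Amd1 shares sequence with Amd2 and the Zscan4, Tdpoz and Usp17l genes are near copies within their families, so single values of these are uncertain. The summed FPKM of the 11 measured members of those families was 236 with siEsrrb and 13.3 with siNT in 3dESC, and 1.37 with DMSO, so the controls also stood apart.

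For lists, the members past the limma test with pooled controls were as follows. All 16 of 16 2-cell-like members rose (16 rose and 0 fell when adjusted over the list alone). The 2-cell-like list had a camera adjusted p = 7.48e-30, and adjusted p = 0.497 with an estimated correlation. Of the primitive endoderm markers 20 of 22 measured members rose, 0 fell and 2 did not pass (22 rose and 0 fell when adjusted over the list alone). The endoderm list had a camera adjusted p = 4.53e-30, and adjusted p = 0.497 with an estimated correlation. In the naive list 1 of 25 measured members rose, 9 fell and 15 did not pass (2 rose and 17 fell when adjusted over the list alone; Esrrb, the target, is 1 of the falls). The naive list had a camera adjusted p = 3.24e-10, and adjusted p = 0.497 with an estimated correlation. Trophoblast markers included Rhox9 (2.35), Krt18 (2.26) and Krt7 (2.22), and 7 of 20 measured members rose, 0 fell and 13 did not pass (12 rose and 1 fell when adjusted over the list alone). The trophoblast list had a camera adjusted p = 1.33e-09, and adjusted p = 0.497 with an estimated correlation. YAP targets included Ctgf (2.33) and Cyr61 (1.82), and 6 of 15 measured members rose, 0 fell and 9 did not pass (8 rose and 1 fell when adjusted over the list alone). The YAP list had a camera adjusted p = 7.16e-06, and adjusted p = 0.650 with an estimated correlation. In the epithelial list 4 of 18 measured members rose, 0 fell and 14 did not pass (8 rose and 0 fell when adjusted over the list alone), with Krt8 (2.08) and Cldn6 (1.92). The epithelial list had a camera adjusted p = 3.54e-07, and adjusted p = 0.497 with an estimated correlation.

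Metabolic and stress lists had medians nearer to 0. Oxidative phosphorylation genes had a median of -0.20 against siNT, outside the -0.11 to 0.028 of random lists, and -0.16 in EPSC. The 3dESC controls differed by 0.18 in this list (DMSO over siNT). Of glycolysis genes 0 of 21 measured members rose, 1 fell and 20 did not pass (1 rose and 7 fell when adjusted over the list alone), with Pfkp (-1.73), a phosphofructokinase. The glycolysis list had a camera adjusted p = 6.94e-06, and adjusted p = 0.497 with an estimated correlation. Of hypoxia genes 1 of 18 measured members rose, 1 fell and 16 did not pass (2 rose and 5 fell when adjusted over the list alone), with P4ha2 (1.15) and Bnip3 (-1.02). The hypoxia list had a camera adjusted p = 0.0153, and adjusted p = 0.650 with an estimated correlation. The hypoxia median was -0.49 against siNT, but the controls themselves differed by -0.40 (DMSO over siNT). In the integrated stress response list 0 of 21 measured members rose, 3 fell and 18 did not pass (2 rose and 8 fell when adjusted over the list alone), with Chac1 (-1.21). The integrated stress list had a camera adjusted p = 7.92e-06, and adjusted p = 0.497 with an estimated correlation. Heat shock genes included Cryab (2.21) and Hspa1a (2.09), and 3 of 15 measured members rose, 0 fell and 12 did not pass (5 rose and 0 fell when adjusted over the list alone). The heat shock list had a camera adjusted p = 0.0390, and adjusted p = 0.497 with an estimated correlation. Among imprinted genes H19 (2.65) was the member that rose, of 22 (3 rose and 0 fell when adjusted over the list alone). The imprinted list had a camera adjusted p = 0.0102, and adjusted p = 0.497 with an estimated correlation. Of p53 targets 1 of 23 measured members rose, 0 fell and 22 did not pass (2 rose and 0 fell when adjusted over the list alone; median 0.30). The p53 list had a camera adjusted p = 0.0376, and adjusted p = 0.751 with an estimated correlation. Against siNT alone, which stood above DMSO in this list (DMSO over siNT -0.47), the p53 median was 0.052, inside the -0.15 to 0.15 of random lists. In the unfolded protein response list 1 of 18 measured members rose, 0 fell and 17 did not pass (4 rose and 0 fell when adjusted over the list alone; median 0.41). The unfolded protein list had a camera adjusted p = 4.80e-06, and adjusted p = 0.650 with an estimated correlation. Its median against siNT alone was 0.28, and the controls differed by -0.28 (DMSO over siNT). The median and mean of the pooled fit differed in sign for the formative (-0.085 and 0.12), ERK (-0.032 and 0.049), NRF2 and AHR (-0.067 and 0.014) and DNA methylation lists (0.044 and -0.085).

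In all, 320 genes were at least 2-fold higher and 196 at least 2-fold lower in 3dESC siEsrrb than in siNT. With the DMSO and siNT libraries pooled as 2 controls, limma called 319 rises and 127 falls, which included 250 of the 320 and 83 of the 196. The ratios rest on 1 library against 1, and the pooled test assumes that the lone treated library varies like the controls. For the siEsrrb effect in 3dESC at pseudocounts of 0.1 and 5, the count of genes at least 2-fold apart was 899 and 176, in place of 516 at 1.

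The same siRNA was compared in EPSC, where Esrrb was 29.8% lower than with siNT, against 67.9% lower in 3dESC. That EPSC fall did not pass the limma test with pooled controls. Whether the changes that follow come from lower Esrrb was not tested. H19, an imprinted non-coding RNA, had the highest ratio, 313 FPKM against 5.95 with siNT (log2 ratio 5.50, limma adjusted p = 6.26e-07 with pooled controls). The keratin genes Krt8 (2.68), Krt18 (2.45) and Krt7 (2.48) and the homeobox genes Rhox6 (2.80) and Rhox9 (2.75) were higher, all of them also in the trophoblast list, where 8 of 20 members were at least 2-fold higher. All 16 2-cell-like members were at least 2-fold higher (median log2 ratio 1.65; without the filter 16 of 24, median 1.25), with Zscan4c (3.49), Zscan4a (3.36) and Zscan4f (2.68). Of the imprinted genes 10 of 22 were at least 2-fold higher (median 0.81), with Cdkn1c, a cell cycle inhibitor, at 2.35 and Peg10 at 1.76.

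Among the 8 highest was also the non-coding Rmrp (4.60), which did not pass. The 8 lowest were Hotairm1 (-3.16), which passed, and Amd2 (-1.56), Slc1a1 (-1.49), Nupr1 (-1.42), Chac1 (-1.41), Cox7a1 (-1.37), Tmem191c (-1.33) and Dazl (-1.25), which did not. H19 aside, Rmrp and Hotairm1 are non-coding too, and their jumps between single libraries are uncertain. In counts, 172 genes were at least 2-fold higher and 44 at least 2-fold lower, and the limma test with pooled controls called 46 rises and 3 falls, all of them among these. Both rest on 1 treated library. A test of whether the siEsrrb effect differs between the states, added after seeing the data, called 3 genes with limma and pooled controls.

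By list in the pooled test, 2-cell-like genes had 6 rises of 16 (16 rose and 0 fell when adjusted over the list alone). The 2-cell-like list had a camera adjusted p = 1.04e-30, and adjusted p = 0.534 with an estimated correlation. For imprinted genes 4 of 22 measured members rose, 0 fell and 18 did not pass (11 rose and 0 fell when adjusted over the list alone), and for trophoblast markers 5 of 20 measured members rose, 0 fell and 15 did not pass (9 rose and 0 fell when adjusted over the list alone). The imprinted list had a camera adjusted p = 1.10e-15, and adjusted p = 0.451 with an estimated correlation. The trophoblast list had a camera adjusted p = 1.23e-11, and adjusted p = 0.534 with an estimated correlation. Of the primitive endoderm markers 2 of 22 measured members rose, 0 fell and 20 did not pass (13 rose and 0 fell when adjusted over the list alone), with Cubn (1.73). The endoderm list had a camera adjusted p = 2.02e-14, and adjusted p = 0.534 with an estimated correlation. In the ERK list 1 of 22 measured members rose, 0 fell and 21 did not pass (5 rose and 1 fell when adjusted over the list alone), with Fgfbp1 (2.20). The ERK list had a camera adjusted p = 0.00187, and adjusted p = 0.552 with an estimated correlation. The ERK median was 0.45 against siNT and 0.18 against DMSO, as the controls differed by 0.29 (DMSO over siNT). Naive genes had a median log2 ratio of -0.27, with 0 rises and 0 falls (2 rose and 0 fell when adjusted over the list alone). The naive list had a camera adjusted p = 0.00239, and adjusted p = 0.534 with an estimated correlation. The median, mean or camera direction differed in sign for the mesoderm, fatty acid, hypoxia, estrogen receptor, Polycomb and housekeeping lists.

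Over both states together, the limma fit called 4 genes for siEsrrb against siNT, with 1164 at an unadjusted p under 0.05. Krt18 rose by log2 2.36 ± 0.18, adjusted p = 0.0191 and Rhox9 by 2.55 ± 0.24, adjusted p = 0.0411. The small nucleolar RNA Snora81 fell (-8.09 ± 0.27, adjusted p = 0.000104) and the unnamed model 3830417A13Rik rose by 2.29 ± 0.22, adjusted p = 0.0411; both fall outside the naming rule and were chosen after their values were seen. Snora81 was listed at 195 and 375 FPKM in the siNT libraries and at 0 in the other libraries of that table, and as a short RNA its values are uncertain. No list had more than 2 members past the test. Adjusted over the list alone, 16 of 16 2-cell-like genes rose, as did 9 imprinted, 8 trophoblast, 7 epithelial and 5 primitive endoderm genes, and 6 germ line and 6 integrated stress genes fell. The 2-cell-like list had a camera adjusted p = 1.75e-21, and adjusted p = 0.437 with an estimated correlation. The imprinted list had a camera adjusted p = 1.36e-06, and adjusted p = 0.466 with an estimated correlation. The oxidative phosphorylation list had no member called and a median of -0.17. Its camera adjusted p was 1.08e-10, and 0.437 with an estimated correlation. For the trophoblast, epithelial, endoderm, germ line and integrated stress lists the camera adjusted p were 8.81e-09, 1.89e-08, 3.36e-10, 0.00120 and 2.59e-06, and with an estimated correlation 0.437, 0.294, 0.535, 0.535 and 0.437. The controls also differed in the lists that fell. For germ line genes the siEsrrb medians were -0.37 in 3dESC and -0.16 in EPSC, and DMSO over siNT gave -0.33 and -0.045. For integrated stress genes the siEsrrb medians were -0.47 and -0.34, and DMSO over siNT gave -0.087 and -0.27. Signs differed between median, mean and camera for the neural, Wnt, fatty acid, DNA methylation and housekeeping lists. Leaving out any of these siRNA libraries leaves its arm with 1 library, so such fits are no check of an effect over both states.

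DES against DMSO in 3dESC asks what the ligand does in the same cells. Primitive endoderm markers were higher, 21 of 22 at least 2-fold (median log2 ratio 2.04), with the endoderm transcription factors Gata6 (2.67) and Sox7 (2.46) and the receptor gene Pdgfra (2.48). Glycolysis genes were lower, 10 of 21 at least 2-fold (median -0.95), with Pfkp at -3.02, the lactate transporter gene Slc16a3 at -2.40, Pgk1 at -2.08 and Tpi1 at -2.02. Genes of the hypoxia response were lower too, such as Bnip3 (-3.48) and Egln3 (-2.33). Targets of p53 were higher, 12 of 23 at least 2-fold (median 1.14), with Perp (3.02), Plk2 (3.01), Ddit4l (2.13) and Mdm2 (2.07). The DMSO library stood low in these genes, by a median of -0.47 against siNT, and the median against pooled controls was 0.84. Naive pluripotency genes were lower, 10 of 25 at least 2-fold (median -0.91), with Nr0b1 (-2.35), Zfp42 (-1.86) and Fgf4 (-1.85).

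The other genes among the 8 highest were Zscan4d (2.88), Zscan4c (2.88), Hotairm1 (2.79) and Ctgf (2.74), which passed the limma test with pooled controls, and Amd1 (5.20) and Entpd4b (3.43), which did not and have close copies. Among the 8 lowest, all of which passed, were the stress genes Chac1 (-3.23) and Nupr1 (-3.17), with Ndufa4l2 (-4.11), A2m (-3.71), Upp1 (-2.86) and Ier3 (-2.69). Ndufa4l2 had the lowest log2 ratio, -4.11, falling from 17.9 to 0.0931 FPKM (pooled estimate -4.52 ± 0.31, adjusted p = 0.000183). A total of 493 genes were at least 2-fold higher and 332 at least 2-fold lower. Limma with pooled controls called 606 rises and 606 falls, which included 379 of the 493 and 283 of the 332. A single DES library stands behind each of these ratios. For the DES effect in 3dESC, 1368 and 290 genes were at least 2-fold apart at pseudocounts of 0.1 and 5, in place of 825 at 1.

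In the pooled test, 20 of 22 measured members rose, 0 fell and 2 did not pass among primitive endoderm markers (21 rose and 0 fell when adjusted over the list alone). The endoderm list had a camera adjusted p = 4.95e-23, and adjusted p = 0.714 with an estimated correlation. In the naive list 1 of 25 measured members rose, 14 fell and 10 did not pass (1 rose and 18 fell when adjusted over the list alone). The naive list had a camera adjusted p = 1.91e-10, and adjusted p = 0.714 with an estimated correlation. For glycolysis 0 of 21 measured members rose, 15 fell and 6 did not pass (0 rose and 19 fell when adjusted over the list alone). The glycolysis list had a camera adjusted p = 8.79e-16, and adjusted p = 0.714 with an estimated correlation. Hypoxia genes gave a like count: 0 of 18 measured members rose, 12 fell and 6 did not pass (1 rose and 14 fell when adjusted over the list alone). The hypoxia list had a camera adjusted p = 1.83e-10, and adjusted p = 0.714 with an estimated correlation. Of p53 targets 11 of 23 measured members rose, 0 fell and 12 did not pass (16 rose and 0 fell when adjusted over the list alone). The p53 list had a camera adjusted p = 3.37e-08, and adjusted p = 0.755 with an estimated correlation. The 2-cell-like list had 12 rises of 16, at a median log2 ratio of 1.83, or 1.49 for 24 members without the filter (16 rose and 0 fell when adjusted over the list alone). The 2-cell-like list had a camera adjusted p = 2.97e-11, and adjusted p = 0.746 with an estimated correlation. DMSO stood low in this list too (DMSO over siNT -0.53), and the summed FPKM of the Zscan4, Tdpoz and Usp17l members was 47.2 with DES against 1.37 with DMSO and 13.3 with siNT.

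Protein stress lists moved in opposite directions. In the integrated stress response list 0 of 21 measured members rose, 11 fell and 10 did not pass (1 rose and 12 fell when adjusted over the list alone), with Stc2 (-2.30) and Ddit3 (-1.97). The integrated stress list had a camera adjusted p = 5.34e-08, and adjusted p = 0.714 with an estimated correlation. In the unfolded protein response list 6 of 18 measured members rose, 0 fell and 12 did not pass (9 rose and 0 fell when adjusted over the list alone), with the chaperone genes Calr (1.28) and Hspa5 (1.20). The unfolded protein list had a camera adjusted p = 1.37e-06, and adjusted p = 0.755 with an estimated correlation. DMSO stood below siNT in the unfolded protein and YAP lists (medians -0.28 and -0.30). YAP targets included Ptpn14 (2.37) and Cyr61 (2.10), and 5 of 15 measured members rose, 0 fell and 10 did not pass (7 rose and 2 fell when adjusted over the list alone). The YAP list had a camera adjusted p = 0.00228, and adjusted p = 0.755 with an estimated correlation. Of the formative genes Otx2 (-2.03) and Fgf15 (-2.00) fell and Sox3 (1.70) rose, and of the Nodal targets Lefty2 (-1.82) fell. In these lists and in those for Wnt and estrogen targets the median and mean of the pooled fit differed in sign (formative 0.10 and -0.10, Nodal 0.021 and -0.12, Wnt -0.038 and 0.039, estrogen 0.10 and -0.075). Estrogen targets had 1 member at least 2-fold lower, Stc2, and none at least 2-fold higher of 11.

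In EPSC the list medians under DES ran from -0.29 to 0.28, the values of the mesoderm and Hox lists with 6 and 8 measured members. Also away from 0 were NRF2 and AHR targets (0.26, with Tiparp at 0.51 and Srxn1 at 0.43), imprinted genes (0.23, with Phlda2 at 1.58 and H19 at 1.06), p53 targets (0.17) and the integrated stress response (-0.17, with Chac1 at -1.23), each outside the central 95% of random lists. The EPSC controls differed by like amounts in some of these lists (DMSO over siNT -0.27 for integrated stress, -0.31 for Hox, 0.19 for NRF2 and AHR, 0.13 for imprinted genes and -0.12 for p53). Formative, germ line, Nodal and naive genes also lay outside (0.16, -0.14, 0.13 and -0.10), as did some others, while primitive endoderm and 2-cell-like genes lay inside (0.032 and 0.13). The 8 highest genes were Amd1 (4.83), Phlda2 (1.58), Rhox9 (1.30), Calca (1.28), Ifitm1 (1.14), Enpp3 (1.13), H19 (1.06) and B2m (1.02), and among the lowest were Rpph1 (-1.83), Khdc3 (-1.67), Synj2bp (-1.64), Ly6a (-1.61), Hist1h4i (-1.59), Ckmt1 (-1.59) and Crxos (-1.43). Of all genes 22 were at least 2-fold higher and 48 at least 2-fold lower. Limma with pooled controls called 0, with 402 at an unadjusted p under 0.05, and the median, mean or camera direction differed in sign for the trophoblast, Wnt, Nodal, YAP, p53, heat shock, proliferation and housekeeping lists.

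Over both states, limma called 0 genes for DES against DMSO, with 1021 at an unadjusted p under 0.05. Adjusted over the list alone, 7 integrated stress response genes fell and 3 primitive endoderm markers rose. The integrated stress list had a camera adjusted p = 7.54e-09, and adjusted p = 0.570 with an estimated correlation. The endoderm list had a camera adjusted p = 7.54e-09, and adjusted p = 0.570 with an estimated correlation. Signs differed between median, mean and camera for the formative, fatty acid, genome architecture and DNA methylation lists. The same test of the difference between states, with pooled controls and added after seeing the data, called 140 genes for DES. Leaving out the EPSC DES library leaves the DES arm with its 3dESC library alone. Such a fit no longer gives an effect over both states, so its calls are no check of this one. In EPSC the dose and the time with DES or siRNA are not given in the sources used here, while 20 µM DES and 50 nM siRNA are stated for 3dESC.

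**Figure D3:**
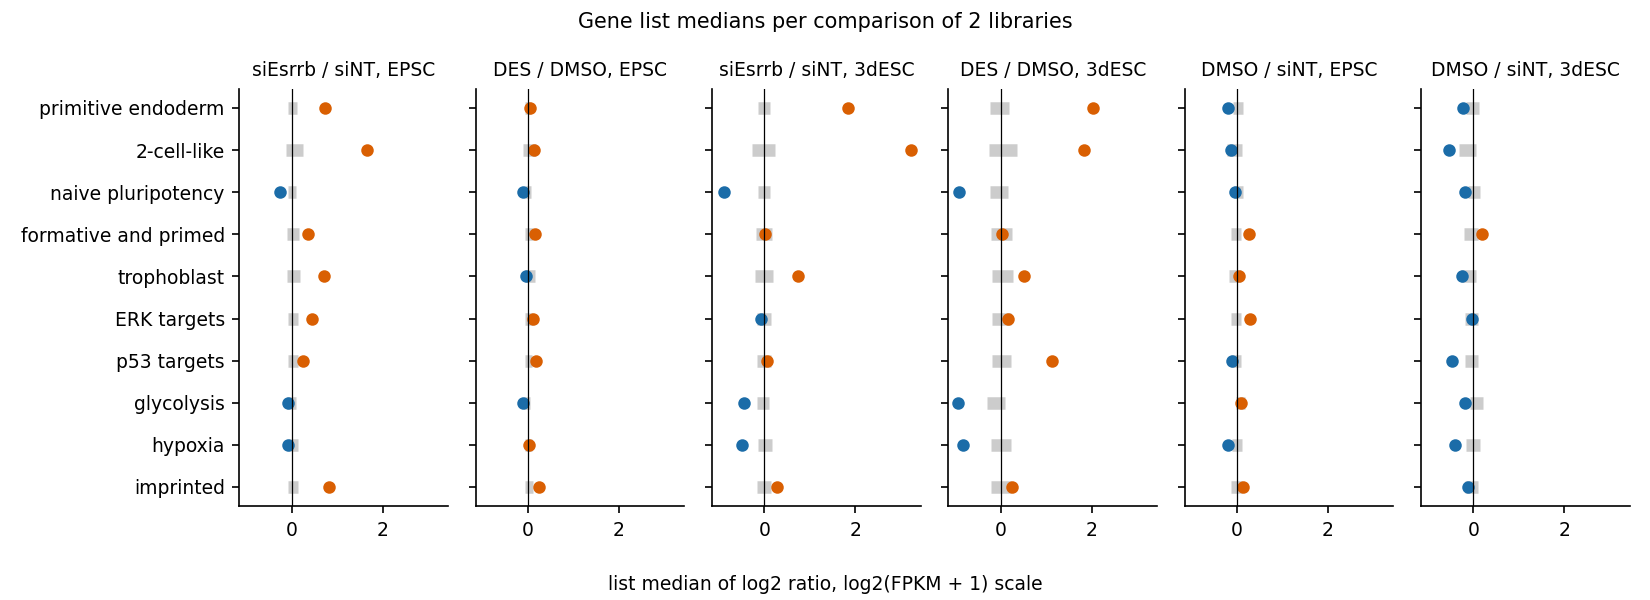
Points give the median log2 ratio (horizontal axis) of 10 gene lists in 6 panels, orange at or above 0 and blue below 0. The panels are siEsrrb over siNT and DES over DMSO in EPSC and in 3dESC, and the DMSO over siNT controls of each state. Gray bars give the central 95% of medians of 10000 random lists of matched expression. In 3dESC the primitive endoderm list stands at 1.83 under siEsrrb and 2.04 under DES, and glycolysis at -0.44 and -0.95.

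Knockdown and ligand were then set side by side in 3dESC, in which they share no library. The primitive endoderm list had medians of 1.83 and 2.04 under siEsrrb and DES, and the naive list -0.88 and -0.91. Across 11783 genes the ratios had a Pearson r of 0.65 and a Spearman rho of 0.64, described without a p since genes are not independent replicates. At least 2-fold higher under both were 205 genes, against 13.4 by chance from the single counts, and at least 2-fold lower under both 98, against 5.52, while 6 genes went in opposite directions. In EPSC the r was 0.31, between the siEsrrb effects of the 2 states 0.45 and between the DES effects 0.15, 3 more relations of the same family.

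A test of DES minus siEsrrb in 3dESC, chosen after seeing the data, called 16 genes with limma, 2 up and 14 down. Each side is 1 library, the spread comes from the control pairs alone, and vehicle and transfection differ between the sides, so the calls cannot be put down to DES alone. Lower in the DES library were the glycolysis and glycogen genes Pfkp (-1.62), Aldoc (-2.28), Pgm2 (-1.47) and Slc16a3 (-1.81) and the hypoxia and stress genes Bnip3 (-2.39), Egln3 (-2.40), Ndufa4l2 (-3.09) and Ier3 (-2.33), with A2m (-2.00), Krt18 (-1.69), Rhox9 (-2.20), Tjp3 (-1.68), Rimklb (-1.57) and Pisd-ps1 (-4.28), and higher were Perp (1.89) and Fbp2 (1.70). In the glycolysis list 3 members were called and 11 fell when adjusted over the list alone (median -0.69). In this test the glycolysis list had a camera adjusted p = 1.10e-16, and adjusted p = 0.607 with an estimated correlation. The hypoxia list had 2 and 11 (median -0.89). In this test the hypoxia list had a camera adjusted p = 8.80e-16, and adjusted p = 0.655 with an estimated correlation. All 16 2-cell-like genes were lower in the DES library when adjusted over the list alone (median -2.05), and the primitive endoderm median was -0.032. In this test the 2-cell-like list had a camera adjusted p = 5.00e-21, and adjusted p = 0.675 with an estimated correlation. These values hold the gap between the 2 controls. Against their own controls the DES and siEsrrb medians were -0.95 and -0.44 for glycolysis, -0.84 and -0.49 for hypoxia, 1.83 and 3.23 for 2-cell-like genes and 2.04 and 1.83 for primitive endoderm.

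**Figure D4:**
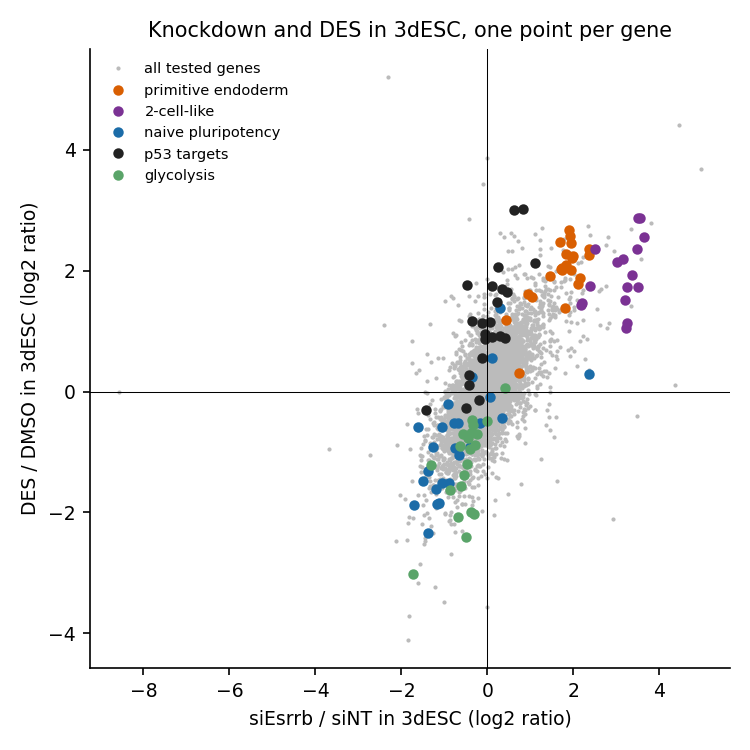
Each point is a gene, with its log2 ratio of siEsrrb over siNT (horizontal axis) against that of DES over DMSO (vertical axis) in 3dESC, for 11783 genes, and colors mark 5 gene lists. The primitive endoderm genes lie to the upper right (medians 1.83 and 2.04) and the glycolysis genes below 0 on the DES axis (median -0.95).

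Whether the treatments held cells back was asked with the genes at least 2-fold apart between day 3 and EPSC in the time course and measured in both tables, 390 higher and 411 lower at day 3, which share no library with the treatments. In 3dESC the higher genes had a median log2 ratio of -0.10 under siEsrrb and -0.20 under DES, and the lower genes -0.086 and 0.069. Random lists of matched expression gave -0.055 to 0.026 and -0.034 to 0.077 for the higher genes. For the lower genes they gave -0.052 to 0.027 and -0.027 to 0.083. Of these medians only that of the lower genes under DES lay inside. The higher list under siEsrrb changed sign, to 0.076, when its genes were taken from the DMSO arm, and that under DES, to 0.0079, when taken from the siNT arm. In EPSC, an addition made after seeing the data, the higher genes stood at 0.39 under siEsrrb and 0.16 under DES, and the lower genes at -0.21 and -0.12. The EPSC controls differed by 0.16 and -0.22 for DMSO over siNT in the same genes. The EPSC medians under treatment and those between the controls all lay outside the ranges of random lists.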

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

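The tests of the difference between states, the counts of other splits and the tests of explanations in this part were chosen only after the result was seen. A test of whether the siEsrrb effect differs between 3dESC and EPSC, in the limma fit with pooled controls, called 3 genes, H19 (-2.85 ± 0.23, adjusted p = 0.00261), Hotairm1 (6.95 ± 0.32, adjusted p = 3.49e-05) and the pseudogene Pisd-ps1 (4.41 ± 0.40, adjusted p = 0.00539). Pisd-ps1 stood at 20.1 FPKM in 3dESC siEsrrb and below 0.1 FPKM in the other 7 libraries of that table. The same test of the DES effect called 140 genes, 65 higher and 75 lower in 3dESC than in EPSC. Primitive endoderm markers gave 14 of the rises, such as Gata6 (3.31) and Col4a1 (3.14). The endoderm list had a camera adjusted p = 4.34e-26, and adjusted p = 0.720 with an estimated correlation. Glycolysis gave 6 and hypoxia 5 of the falls, such as Bnip3 (-3.50), Egln3 (-3.18) and Pfkp (-2.79), and naive pluripotency 4.

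Primitive endoderm markers were higher under both siEsrrb and DES in 3dESC, with 19 members at least 2-fold higher under both. A single scaling factor per library is argued against, since over all genes the median log2 ratio was -0.011 under siEsrrb and 0.016 under DES. After centring each library on its median the lower of the 2 list medians was 1.80, but such centring could move it little. Differences between cultures in spontaneous endoderm stay open: the 3dESC over EPSC median of the 16 members measured in both tables was 2.09 with DMSO, 1.64 with siNT and 0.64 in the time course, a range of 1.46. Within 3dESC the 2 controls differed by -0.24 in the whole list, less than the 1.83 and 2.04 under treatment, but each condition has 1 culture. Loss of Esrrb activity, by siRNA or by the ligand, may account for the shared 19 members, which is a hypothesis found on these data. Cells of an endoderm type are a candidate source, with Apoe at 998, Sparc at 482 and Col4a1 at 424 FPKM in 3dESC siEsrrb against 601, 174 and 107 in siNT, though 14 of the 22 measured markers were at 1 FPKM or more in EPSC siNT already and 1 is in another list.

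Glycolysis genes were lower under DES than under siEsrrb in 3dESC, by a median of -0.69 (-0.95 and -0.44 against their own controls) with adjusted p = 0.607 with an estimated correlation. A larger endoderm share under DES is argued against, since the primitive endoderm median of DES minus siEsrrb was -0.032 (2.04 and 1.83 against their own controls). A weaker loss of Esrrb activity under siEsrrb and a further action of DES cannot be told apart with the -0.69, as 1 library stands for each. Differences in density or oxygen between cultures could add to it, and the 3dESC DMSO and siNT cultures differed by -0.19 in the list. No library tests DES without Esrrb.

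The 2-cell-like genes were higher under siEsrrb in both states. Reads passing between copies are argued against as the whole cause, since the summed FPKM of the Zscan4, Tdpoz and Usp17l members was higher by 3.96 log2 or more in both states. Low depth of the 3dESC siEsrrb library is argued against too, since the list median was 1.65 in EPSC, where the siEsrrb library is the deepest. Chance differences between cultures in the share of 2-cell-like cells could contribute and stay open, as the 3dESC DMSO and siNT cultures differed by -0.53 and summed FPKM was 1.37 and 13.3 in them. A link with Esrrb loss is a hypothesis.

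For the state effect, the 8 splits within arms are too few for a share under 0.05; the real split gave 3637 genes, with 1 split reaching that count, itself, and 0 for the highest other. Without the arm term, of 35 splits of the 8 libraries 1 gave as many, the real one with 3178 genes, and the highest other gave 1. These splits ignore the arms, so they exclude chance only if libraries of an arm are no more alike than others.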

How the results depend on the processing

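The tests in this part were planned, apart from those of the difference between states, of DES minus siEsrrb, between controls and of time course lists in EPSC, which were chosen only after the result was seen. Of the values that answer a comparison, 46 kept their side and direction, 26 moved, 11 lost and 2 gained calls, and 2 reversed. Of the values of named genes 7837 stayed and 718 moved, with 163 falling below and 44 passing the threshold, and of list values 1790 stayed, 79 moved, 76 lost and 19 gained a call. The list of BMP and Id genes under siEsrrb in EPSC reversed, to -0.091 at a minimum of 5 FPKM. The state effect called 861 genes when also at least 2-fold, 2332 from the 4 control libraries, and 2102 to 3477 without an arm (2102 without siEsrrb, 2328 without DMSO, 2365 without siNT), where fewer libraries were fitted. The siEsrrb effect over both states called 1 gene with no filter, 2 at a minimum of 5 FPKM, 8 without the trend, and 1 to 2 without a library (1 without EPSC siNT); the DES effect called 0 to 358, the highest without EPSC DES. At pseudocounts of 0.1 and 5 and a minimum of 5 FPKM, genes at least 2-fold apart numbered 899, 176 and 264 for the siEsrrb effect in 3dESC, 514, 55 and 110 for the siEsrrb effect in EPSC, 1368, 290 and 485 for the DES effect in 3dESC, 243, 10 and 27 for the DES effect in EPSC, and 1336, 286 and 462 for the time course, day 3 against EPSC; the stricter minimum tests fewer genes. With pooled controls the count was 49 for siEsrrb in EPSC and 0 for DES in EPSC, by limma, with 402 at an unadjusted p under 0.05. Genes higher in the time course had a median under siEsrrb of 0.076 with the list from the DMSO arm, a reversal, and under DES of -0.12 with a 4-fold list and 0.0079 with the list from the siNT arm, also a reversal. Genes lower in the time course had under siEsrrb -0.23 with a 4-fold list, -0.15 with the DMSO arm list, -0.046 at a pseudocount of 0.1 and -0.037 at a minimum of 5 FPKM, and under DES 0.13 with a 4-fold list and 0.14 at a pseudocount of 0.1. The r between siEsrrb and DES effects was 0.61 at a pseudocount of 0.1 and 0.69 at a minimum of 5 FPKM. For these the cause was not tested. The state fit called 3178 genes without the arm term. Depth is unknown, so genes of low FPKM carry an unknown counting error.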

Other observations

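The tests in this part, of time course lists in EPSC and between controls, were chosen only after the result was seen. Genes for imprinting and hormone response gave further values. H19 stood at 313 FPKM in EPSC siEsrrb against 5.95 in EPSC siNT and 6.36 in EPSC DMSO, and at 300.3 in 3dESC siEsrrb against 47.1 in 3dESC siNT. In the time course it stood at 33.8, 119, 78.9 and 31.4 FPKM. Of the receptors that DES binds, Esrra ran from 14.3 to 24.7 FPKM over the first table, while Esr1 stayed at or below 0.0617 and Esrrg at or below 0.0255.

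Some genes had jumps between libraries of the same state. Amd1 stood at 0.0430 FPKM in EPSC DMSO and 30.7 in EPSC siNT, and at 0.178 and 11.9 in the 3dESC controls, and its relative Amd2 at 64.2, 32.3, 59.4 and 30.1 in the same order. Snora81 was listed at 393 and 292 FPKM in EPSC and at day 1 of the time course and at 0 at days 2 and 3. Pisd-ps1 stood at 0.0252, 13.0, 12.6 and 0.0533 FPKM in the time course. Hotairm1 was listed at 0 in EPSC siEsrrb, 3dESC DMSO and 3dESC siNT and at 12.9 FPKM in 3dESC siEsrrb.

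The control cultures of a state also differed. DMSO over siNT gave 29 genes at least 2-fold higher and 96 lower in 3dESC, and 41 and 33 in EPSC, with no p. In 3dESC the list medians between these controls included -0.53 for 2-cell-like genes, -0.47 for p53 targets, -0.45 for 7 feeder and fibroblast genes, -0.40 for hypoxia genes and -0.24 for primitive endoderm markers.

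A hypothesis was that knockdown moves EPSC towards the 3dESC profile. Against EPSC DMSO in place of siNT, the genes higher at day 3 had a median of 0.24 in EPSC siEsrrb and the genes lower at day 3 a median of -0.011. The 0.24 lay above the 0.041 to 0.105 of random lists, and the -0.011 lay below their 0.051 to 0.115. With siNT as the control the medians were 0.39 and -0.21. The EPSC controls themselves differed by 0.16 and -0.22, so a shift by knockdown and a difference between cultures cannot be told apart.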
